A study of Mus musculus with 2 samples.

How the data were processed

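RNA sequencing was analysed from 2 cultures of Th17 cells, 1 from wild-type and 1 from lncRNA-GM knockout mice, each collected after 3 days of polarisation of naive CD4+ T cells from spleen. Total RNA was extracted with TRIzol and sequenced on an Illumina HiSeq, per the labels' protocols. Per the submitters' processing notes, Bowtie2 and RSEM were used with GRCm38.p6, without versions; filters, strandedness and read pairing were not given in the sources used here.

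The authors deposited 1 table of 17002 genes with Entrez gene IDs and symbols. Its 2 expression columns were read as FPKM values made by the authors, although the file header says only expression. That unit was inferred because the columns sum to 517664 and 514343 rather than to the fixed total of TPM, and because FPKM times annotated transcript length sums to a total of the size that FPKM gives. The authors' deposited log2 ratio, knockout over wild type per the file headers, was recomputed within 0.001 for all 17002 rows with values of 0 set to 0.01. The authors' deposited p-value is from a comparison of 1 library with 1 library by a test that the sources used here do not name. The authors' deposited FDR, treated as a score, exceeds 1 for 443 genes and so was used only to count genes at their limit. Symbols turned into dates by a spreadsheet (24 rows) were restored from the gene ID.

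The following choices were made before the data were examined. With no counts in the table, the measure was the log2 ratio of FPKM + 1, knockout over wild type, over genes with at least 1 FPKM in 1 library, with a fold of 2 for gene counts and of 1.5 for list members. With 1 library per genotype no test was run. For each list, the median log2 ratio of its measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A total of 31 lists was fixed, covering T helper programmes, Foxo1-activated genes, signalling, metabolism, stress, markers of other cell types and technical controls; 29 had measured members, and mitochondrially encoded genes had no rows in the table. Genes were named by a rule: genes tied to the question (among them Foxo1, Il17a, Il17f, Il23r, Il22 and Foxp3); the 12 highest and 12 lowest ratios with at least 5 FPKM in 1 library, without receptor and immunoglobulin segments, predicted genes and unnamed loci; and of each list up to 2 highest and 2 lowest members past 1.5-fold, or else its 2 most abundant members. Further list members and copies named in the text were chosen after their values were seen. A few genes that the rule or the lists hold are not reported here.

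The other steps were chosen after seeing the data. The deposited p-values of genes listed at 0 in 1 library follow a Poisson comparison of 2 libraries, and solving it gave whole reads within 0.05 for 66 of 66 such genes. With 50.4% of reads in the wild-type library, depth was about 19.4 M fragments in the wild type (quartiles 18.2 and 19.8 over 271 genes with 1 annotated transcript of at least 1500 bases) and 19.1 M in the knockout. Reads were solved for 3728 genes and taken from transcript length for 12885; 389 genes had none. Length-based values lay within 2-fold of the solved ones for 88.0% of solved genes. The reads gave 95% exact (Clopper-Pearson) counting intervals of the ratio, with no pseudocount, so that an interval need not hold the FPKM + 1 ratio of a gene with low values. Reads without molecular identifiers are not independent molecules, and the intervals cover counting error only.

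Near-identical copies were searched with BLAST 2.17.0 as annotated transcripts with at least 95% identity over at least 50% of a transcript, and their FPKM values were summed. Since a far more abundant copy hides any ratio in a sum, the FPKM change of each gene was also set against that of its copies, with 1000 draws that replaced the copies by 1 of the 100 genes nearest to their level, and each family was summed with a counting interval of its reads. Gene coordinates came from the RefSeq gene table for GRCm38.p6, in which 16878 gene IDs (99.3%) were found. Transcripts and exon overlaps came from GENCODE release M21. Without known strandedness, reads of overlapping genes on opposite strands cannot be told apart. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

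The steps were tested on data simulated for this comparison over 10928 genes. The 2-fold rule recovered 93% of 100 genes changed 3-fold and 99% of 100 genes changed 6-fold, with 0 unchanged genes called. The simulated noise was counting error only, without spread between cultures or shared reads between copies. The 0 is therefore not the rate of false calls between 2 cultures. Of 200 random lists with no effect, 7.5% fell outside the central 95%, and a list shifted 1.5-fold reached percentile 100. Read numbers were within 20% of the simulated reads for all 412 genes solved. The simulated p-values came from the formula that was then solved, so this checks the solving step only. Alternatives covered the pseudocount, the FPKM minimum, scaling, the fold, the authors' log2 ratio, list matching, list means, reconstructed reads and summed copies. The level of lncRNA-GM was not analysed here.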

Results

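Naive CD4+ T cells from the spleens of C57BL/6 mice, either wild type or lacking the long non-coding RNA lncRNA-GM, were cultured for 3 days under Th17-polarising conditions, and the RNA of the resulting Th17 cells was sequenced. The data comprised 2 libraries, 1 wild type and 1 lncRNA-GM knockout. Expression was listed for 17002 genes, of which 10998 reached 1 FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) in at least 1 library. Depth, reconstructed from the authors' deposited p-values, was about 19.4 M fragments in the wild-type library and 19.1 M in the knockout library. Each genotype was represented by 1 library, so no replicate spread could be estimated, no test was run, and every difference below describes these 2 libraries without a replicate check. Log2 ratios are knockout over wild type on FPKM + 1, and intervals are 95% exact counting intervals (Clopper-Pearson) on the ratio of reconstructed reads, which cover counting error only. No row was assigned to lncRNA-GM itself, whose level was not analysed here, so the knockout label was not checked by its target.

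The first question, raised by the title of the series, was whether the Th17 programme differed in cells without lncRNA-GM. Both IL-17 genes, which encode the signature cytokines of Th17 cells, were lower in the knockout library. Il17f was 2.76-fold lower, at 1056 FPKM in the wild type and 382 FPKM in the knockout, and Il17a was 2.19-fold lower, at 392 and 178 FPKM. Il23r, the receptor subunit that maintains Th17 cells, was 2.83-fold lower. Il21, an autocrine Th17 cytokine, was 1.87-fold higher in the same library, at 39.9 FPKM in the wild type and 75.5 FPKM in the knockout.

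Of the 17 measured genes in the Th17 list, 7 were at least 1.5-fold lower, 1 was at least 1.5-fold higher and 9 lay within 1.5-fold. Beside Il17f, Il17a and Il23r, the lower genes included the IL-1 receptor Il1r1, the aryl hydrocarbon receptor Ahr and the nuclear receptor Rora, with log2 ratios of −0.87, −0.71 and −0.62. The cytokine Il24 and the transcription factors Maf and Irf4 had log2 ratios of 0.47, 0.48 and 0.51. Stat3, Hif1a and Csf2 had log2 ratios of −0.15, 0.12 and 0.04. The list median was −0.15, at percentile 0.985 among 10000 random lists of matched expression and at percentile 4.19 among random lists without matching, which falls inside the central 95%.

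On GRCm38.p6, Il17a lies on chromosome 1 from 20730905 to 20734496 and Il17f from 20777146 to 20785274. Their log2 ratios were −1.13 (interval −1.19 to −1.08) and −1.47 (interval −1.50 to −1.43). Il23r, on chromosome 6 from 67422932 to 67491855, was at 6.63 FPKM in the wild type and 1.70 FPKM in the knockout. These values rested on about 323 and 81 reads, and the interval of the read ratio ran from −2.34 to −1.62, whereas the log2 ratio on FPKM + 1 was −1.50. Il22, on chromosome 10 from 118204584 to 118210047, was at 46.0 FPKM in the wild type and 67.3 FPKM in the knockout. Its near-identical copy Iltifb was at 20.6 and 9.73 FPKM, and the summed pair had a log2 ratio of 0.21, so the value of Il22 alone is uncertain.

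**Figure D1:**
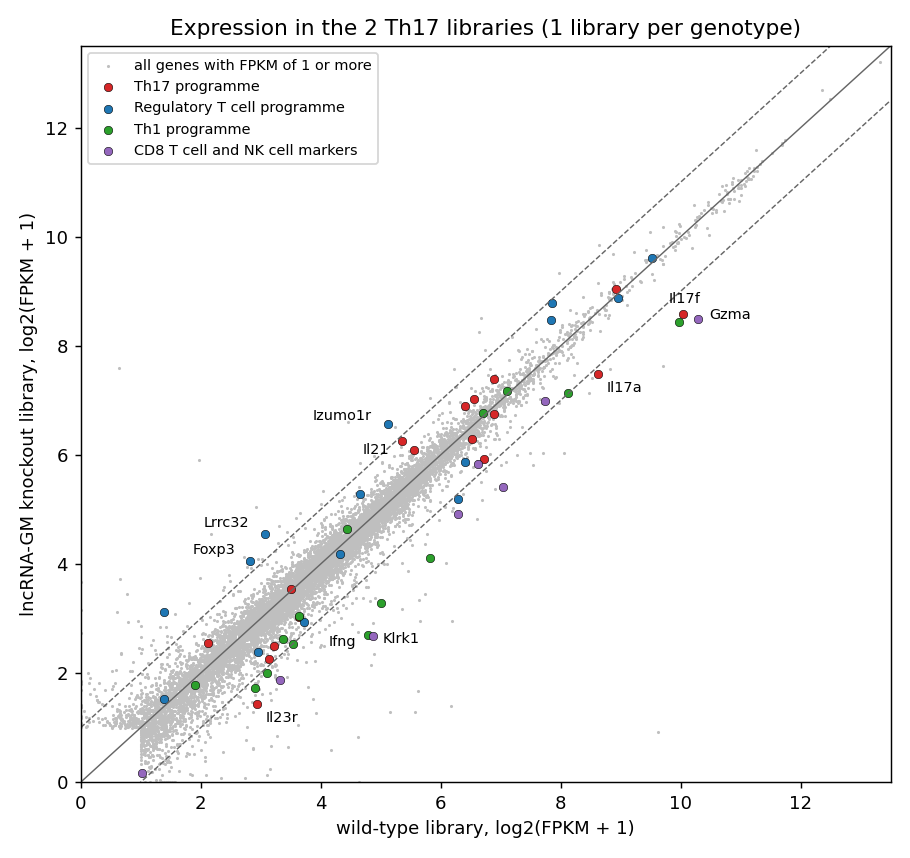
Expression of each gene in the wild-type library (x axis, log2 of FPKM + 1) against the knockout library (y axis, log2 of FPKM + 1). Grey points are the 10998 genes with FPKM of 1 or more in a library, coloured points are measured members of 4 gene lists, the solid line marks equal values and the dashed lines 2-fold differences. Il17a, Il17f, Il23r, Ifng, Gzma and Klrk1 sit below the lower dashed line, and Foxp3, Lrrc32 and Izumo1r sit above the upper one.

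The second question concerned Foxo1, a transcription factor that maintains quiescence and homing of naive T cells and is named in the title as the target of lncRNA-GM. Foxo1 RNA was close to equal in the 2 libraries, at 46.9 FPKM in the wild type and 41.7 FPKM in the knockout. Of 14 measured genes known to be activated by Foxo1, 3 were at least 1.5-fold lower in the knockout and none was at least 1.5-fold higher. The lower genes were the IL-7 receptor Il7r, at 106 and 58.7 FPKM, the pro-apoptotic Bcl2l11, at 17.1 and 10.2 FPKM, and the egress receptor S1pr1, at 34.3 and 22.4 FPKM. Klf2, a transcription factor gene and classical Foxo1 target, had a log2 ratio of 0.31.

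Foxo1 lies on chromosome 3 from 52268337 to 52350109, and its log2 ratio was −0.16 (interval −0.22 to −0.12). The median of the Foxo1-activated genes was −0.18, at percentile 0.39 of matched random lists, and their mean fell at percentile 4.20. None of the 16 genes of the PI3K, Akt, Sgk1, mTOR and Foxo list differed 1.5-fold. The kinase genes Pik3cd and Akt1 were the most abundant of these, with log2 ratios of −0.04 and −0.04. The list median was 0.11, at percentile 97.8, and it stayed outside the central 95% of random lists in 8 of 12 settings. RNA level alone was measured, and the activity of the Foxo1 protein was not.

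Several genes of regulatory T cells, a lineage that like Th17 cells depends on TGF-β, were higher in the knockout library. Foxp3, the lineage transcription factor, was 2.35-fold higher, at 6.08 FPKM in the wild type and 15.6 FPKM in the knockout. Gpr83 was 3.32-fold higher, Lrrc32, which encodes the latent TGF-β receptor GARP, was 2.79-fold higher, and Izumo1r, which encodes folate receptor 4, was 2.73-fold higher. The inhibitory receptor Tigit and the integrin Itgae ran the other way, at 2.12-fold and 1.74-fold lower.

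Of 15 measured genes in the regulatory T cell list, 7 were at least 1.5-fold higher and 2 at least 1.5-fold lower. The costimulatory receptors Tnfrsf4 and Tnfrsf18 went from 230 to 441 FPKM and from 229 to 354 FPKM, and Ikzf4, which encodes Eos, went from 24.1 to 38.1 FPKM. Il10 had a log2 ratio of −0.54, and Ctla4 and Il2ra had log2 ratios of −0.08 and 0.08. The list median was 0.14, at percentile 98.7, and it ran from 0.08 to 0.42 over 12 settings. With a pseudocount of 5 it fell at percentile 95.9, inside the central 95%. Foxp3, on chromosome X from 7579676 to 7595243, had a log2 ratio of 1.23 (interval of the read ratio 1.203 to 1.524), and its exons overlap Flicr on the same strand and Ccdc22 and Ppp1r3f on the opposite strand.

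Genes of the Th1 programme and of cytotoxic lymphocytes were lower in the knockout library, and no measured member of either list was at least 1.5-fold higher. Ifng, the signature Th1 cytokine, was 4.27-fold lower, at 26.8 FPKM in the wild type and 5.51 FPKM in the knockout. Prf1, which encodes perforin, was 3.29-fold lower, and Gzma and Gzmb, which encode granzymes A and B, were 3.50-fold and 2.90-fold lower. Gzma was at 1254 FPKM in the wild type and 358 FPKM in the knockout. Tbx21, which encodes the Th1 transcription factor T-bet, was 1.68-fold lower.

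Of 14 measured Th1 genes, 10 were at least 1.5-fold lower and none at least 1.5-fold higher. The chemokine receptors Cxcr6 and Cxcr3 had log2 ratios of −1.70 and −1.11, and Il12rb2, the inducible IL-12 receptor subunit, went from 279 to 140 FPKM. Runx3, Stat4, Il12rb1 and Hlx lay within 1.5-fold. The median was −0.999, below all 10000 matched random lists, and it was −0.66 with a pseudocount of 5. Markers of CD8 T cells and natural killer (NK) cells were lower too, with 8 of 8 measured genes at least 1.5-fold lower and a median of −1.41, again below all random lists. Cd8a went from 98.1 to 55.7 FPKM and Cd8b1 from 212 to 126 FPKM, although the labels name CD4+ T cells. Klrk1, the activating receptor NKG2D, went from 28.5 to 5.44 FPKM. The pan-T and CD4 markers had no member 1.5-fold apart and a median of 0.07 at percentile 82.2, with Thy1 at 840 and 906 FPKM and Cd2 at 594 and 841 FPKM.

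The other helper programmes differed in direction. Among Th2 genes, 3 of 8 measured members were at least 1.5-fold higher in the knockout and none was lower. Il13, a Th2 effector cytokine, went from 1.68 to 6.19 FPKM, the chemokine receptor Ccr8 went from 5.64 to 16.6 FPKM, and Il4 was listed at 0 in the wild type and at 1.59 FPKM in the knockout. Gata3, the Th2 transcription factor, had a log2 ratio of 0.07. The Th2 median was 0.24 at percentile 99.4. It ran from 0.13 to 0.61 (the mean) over 12 settings and fell inside the central 95% in 2, with no FPKM minimum and, at percentile 88.0, when genes under 5 FPKM were left out. In the follicular helper list, Pdcd1, which encodes PD-1, and Bcl6 were at least 1.5-fold lower among 9 measured genes, with log2 ratios of −0.92 and −0.88, and the median of −0.16 fell at percentile 9.55. Co-inhibitory receptors had a median of −0.37 at percentile 0.20, with Tigit, Pdcd1 and Lag3 at least 1.5-fold lower among 8 measured genes. That median was −0.21 at percentile 3.68, inside the central 95%, with no FPKM minimum, and −0.18 with a pseudocount of 5.

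**Figure D2:**
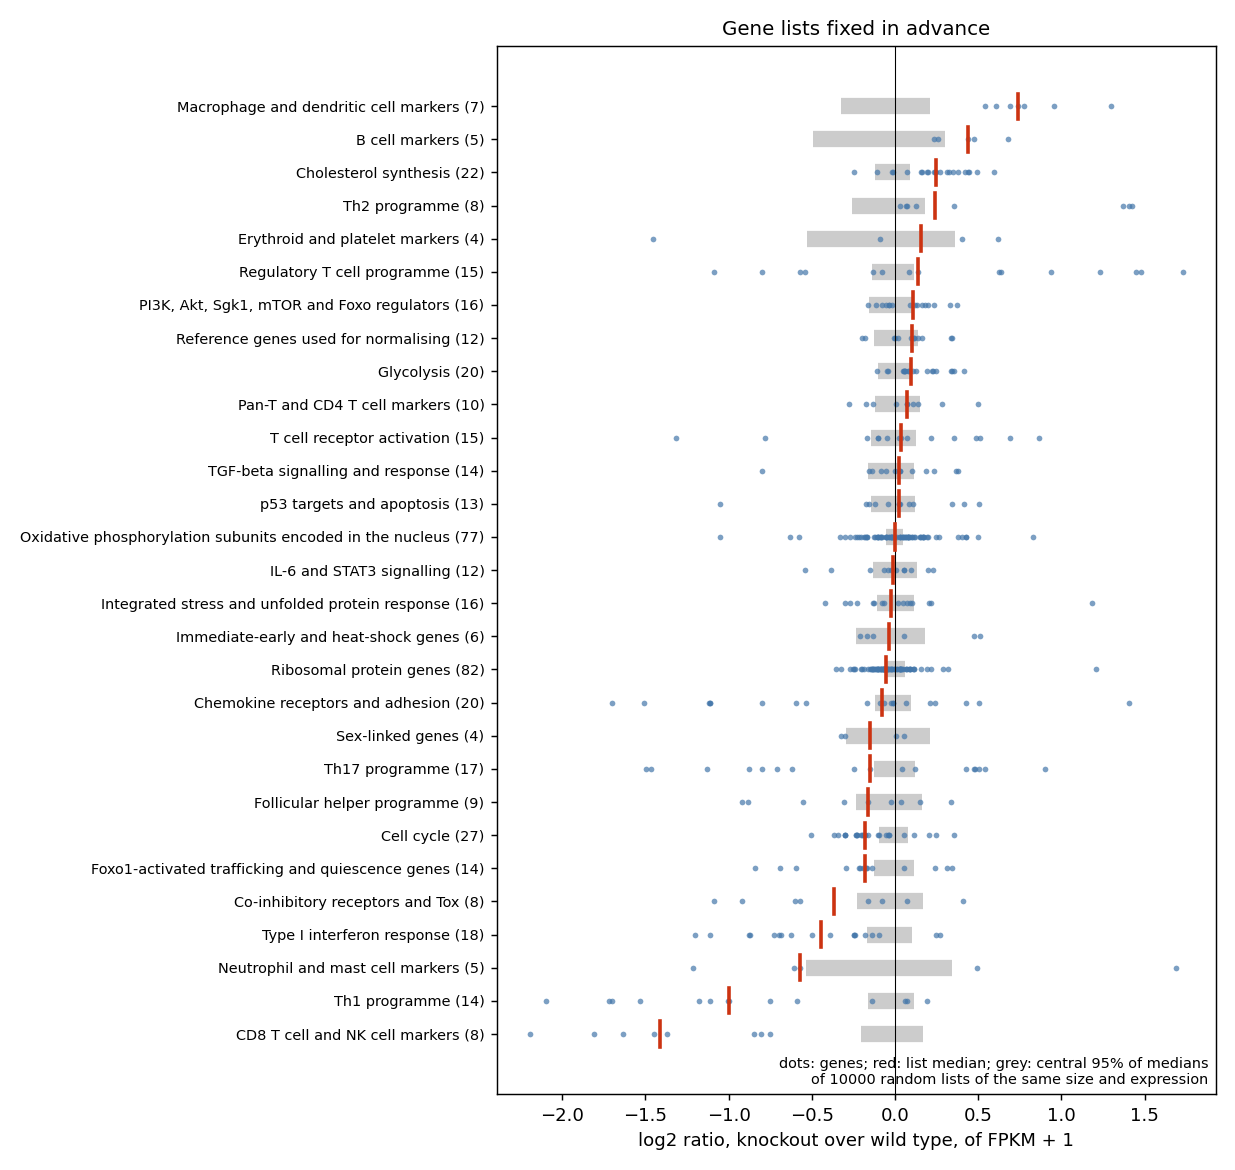
Log2 ratio of knockout over wild type on FPKM + 1 (x axis) for the measured genes of 29 gene lists (rows, number of measured genes in brackets). Dots are genes, red bars list medians, and grey bars the central 95% of medians of 10000 random lists matched on size and expression. The Th1 median of −0.999 and the CD8 and NK median of −1.41 lie far to the left of their grey bars, and the macrophage and dendritic cell median of 0.74 lies to the right.

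Interferon-stimulated genes were lower in the knockout library. Of 18 measured genes in the type I interferon list, 8 were at least 1.5-fold lower and none at least 1.5-fold higher. Usp18, a negative regulator of interferon signalling, was 2.16-fold lower, at 6.67 FPKM in the wild type and 2.55 FPKM in the knockout. Trim30a had a log2 ratio of −1.20, and −1.35 when summed with its near-identical copy Trim30d. The list median was −0.44, below all matched random lists. It ran from −0.73 to −0.21 over 12 settings, with −0.21 at percentile 0.020 for a pseudocount of 5.

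Among signalling lists, the TGF-β list had Itgae as its only member 1.5-fold apart, and its median over 14 genes was 0.03 at percentile 76.7. The IL-6 and STAT3 list had none of 12 members 1.5-fold apart, with Junb and Pim1 at log2 ratios of 0.05 and 0.01 and a median of −0.01 at percentile 43.9. Of 15 measured T cell receptor activation genes, Tnf and Egr1 were at least 1.5-fold higher, with log2 ratios of 0.86 and 0.69. Nr4a2 and Cd44 were at least 1.5-fold lower, with log2 ratios of −1.31 and −0.78, and the list median of 0.04 fell at percentile 77.4. Immediate-early and heat-shock genes had no measured member of 6 at 1.5-fold, with Ier2 at a log2 ratio of 0.48 and a median of −0.04 at percentile 42.8. Among chemokine receptors and adhesion genes, 7 of 20 were at least 1.5-fold lower and 1 was higher. Cxcr6 and Ccr2 had the lowest log2 ratios, −1.70 and −1.51, and Ccr8 the highest, 1.41, with a list median of −0.08 at percentile 11.6. The mean of the members was −0.30 at percentile 0.34, outside the central 95%.

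Genes of cholesterol synthesis were modestly higher in the knockout, with 18 of 22 log2 ratios above 0. A single member passed 1.5-fold, and Hmgcs1, which encodes HMG-CoA synthase, went from 39.9 to 56.6 FPKM. The list median was 0.25, at percentile 100. None of 20 glycolysis genes differed 1.5-fold, and their median was 0.10 at percentile 97.3 and lay outside the central 95% in 2 of 12 settings, with Gapdh and Pkm at log2 ratios of 0.34 and 0.19. Cell-cycle genes were slightly lower, with 22 of 27 log2 ratios below 0, none 1.5-fold apart, Pcna and Ube2c at −0.18 and −0.03, and a median of −0.18 at percentile 0.030 that moved to percentile 4.56 for the mean.

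In the integrated stress and unfolded protein response list, Xbp1, a transcription factor of secretory capacity, was the only one of 16 genes 1.5-fold apart, at 106 FPKM in the wild type and 241 FPKM in the knockout. Its list median was −0.02 at percentile 33.3. Pmaip1, a pro-apoptotic p53 target, was 2.07-fold lower and the only one of 13 p53 and apoptosis genes 1.5-fold apart, with a list median of 0.02 at percentile 68.8. Among 77 nuclear-encoded oxidative phosphorylation genes, Ndufa3 was higher and Cox7b and Cox6b2 were lower by at least 1.5-fold, and the median was 0.00 at percentile 48.2. Ribosomal protein genes had a median of −0.05 at percentile 0.99 over 82 genes, or percentile 19.6 without matching, and only Rpl34, which has a near-identical copy, was 1.5-fold apart.

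Markers of antigen-presenting cells were at low levels and higher in the knockout library. Of 7 measured macrophage and dendritic cell genes, 6 were at least 1.5-fold higher, among them Cd74, the class II invariant chain, at 15.4 FPKM in the wild type and 39.4 FPKM in the knockout, and H2-Ab1, at 10.6 and 21.6 FPKM. Their median was 0.74 at percentile 100, and 0.39 with a pseudocount of 5. The 5 measured B cell markers had a median of 0.44 at percentile 99.4, which ran from 0.18 to 0.71 over 11 settings, with Cd79b at 1.10 and 2.36 FPKM. Of 5 neutrophil and mast cell markers, Ly6g and Cpa3 were lower, with log2 ratios of −1.22 and −0.61, and S100a9 was listed at 0 in the wild type and at 2.23 FPKM in the knockout. Their median of −0.57 fell at percentile 1.76 and stayed outside the central 95% in 7 of 11 settings. Of 4 erythroid and platelet markers, Hba-a2 was higher, Pf4 was listed at 1.74 FPKM in the wild type and at 0 in the knockout, and the median was 0.16 at percentile 88.1, which turned to −0.15 with no FPKM minimum and reached percentile 98.1 with reconstructed reads. None of the 3 γδ T cell markers in the table reached 1 FPKM.

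Reference genes had no member of 12 at 1.5-fold and a median of 0.11 at percentile 94.1, with Gapdh at 5225 and 6612 FPKM and Rplp0 at 3317 and 3300 FPKM. Y-linked genes were expressed in both libraries, with Eif2s3y at 77.8 and 61.9 FPKM and Ddx3y at 15.4 and 12.3 FPKM. The sex-linked list had a median of −0.15 at percentile 15.8. In all, the medians of 15 of 29 lists lay outside the central 95% of random lists, 9 on the lower and 6 on the higher side. By definition 5% would lie outside by chance, and 7.5% of simulated lists with no effect did. The lists share members and genes within a list vary together, so these percentiles describe the libraries and are no test of the genotype.

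Across all 10998 genes, 111 were at least 2-fold higher and 216 at least 2-fold lower in the knockout library, and 10129 genes (92.1%) lay within 1.5-fold. Lower genes with no near-identical copy found included Pianp, at 46.9 FPKM in the wild type and 1.45 FPKM in the knockout, the aspartic protease gene Ctse, at 71.6 and 6.73 FPKM, the surface glycoprotein gene Cd24a, at 49.7 and 6.75 FPKM, and the glycosyltransferase gene Gcnt1, at 27.7 and 3.46 FPKM. Atp6v0e2, Ppp1r14c, the mast cell protease gene Mcpt1 and the NK receptor gene Klra5 had log2 ratios of −2.97, −2.90, −2.66 and −2.58. Of the 12 named genes with the highest ratios, Tgm2, which encodes transglutaminase 2, had the highest level, at 101 FPKM in the wild type and 365 FPKM in the knockout. The metalloelastase gene Mmp12, the chemokine gene Ccl22, Ptprv and Gpr83 had log2 ratios of 2.52, 1.84, 1.76 and 1.73. Macrophages and dendritic cells are known to make Mmp12 and Ccl22, and their markers had a median of 0.74 in the same comparison. Which cells held the Mmp12 and Ccl22 RNA was not tested. Fbxo17 and Fbxo27, which neighbour each other on chromosome 7, had log2 ratios of 2.38 and 1.64.

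Pianp lies on chromosome 6 from 124996720 to 125003096, Ctse on chromosome 1 from 131638314 to 131675507, Tgm2 on chromosome 2 from 158116405 to 158146392, and Fbxo17 on chromosome 7 from 28716749 to 28738145. Their log2 ratios were −4.29 (interval of the read ratio −5.41 to −4.66), −3.23 (interval −3.60 to −3.22), 1.84 (interval 1.82 to 1.89) and 2.38 (interval 2.40 to 2.96). Exons of Tgm2 overlap Rprd1b on the opposite strand.

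The 3 highest and the 2 lowest ratios among the named genes belonged to genes with near-identical copies. These differences fell under 2-fold when the FPKM values of gene and copies were summed. Hmga1b, a copy of the chromatin protein gene Hmga1, had a log2 ratio of 6.96, whereas Hmga1 and Hmga1b together were at 267 FPKM in the wild type and 257 FPKM in the knockout. Ahcy, which encodes adenosylhomocysteinase, had a log2 ratio of 3.92 alone and −0.0012 summed with Gm4737. Rpl34-ps1 was at −8.70 alone and −0.36 with Rpl34, and Eif3j1, listed at 0 in the knockout, was at −0.26 with Eif3j2. Reconstructed reads of these pairs gave other sums, with intervals of 0.53 to 0.60 for Rpl34-ps1 with Rpl34 and −1.16 to −0.97 for Eif3j1 with Eif3j2. The sums of these pairs are therefore uncertain. Hist1h2ai, Zfp966 and Rnaset2b had log2 ratios of 3.07, 2.15 and 2.14 alone and −0.23, 0.12 and 0.02 in the sums, although the copies of Hist1h2ai, at 185 and 146 FPKM, far outweigh it. The NK receptor gene Klrc2 and the class I gene H2-Q2 kept their direction, with −3.86 and −3.79 alone and −2.83 and −3.55 in the sums.

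**Figure D3:**
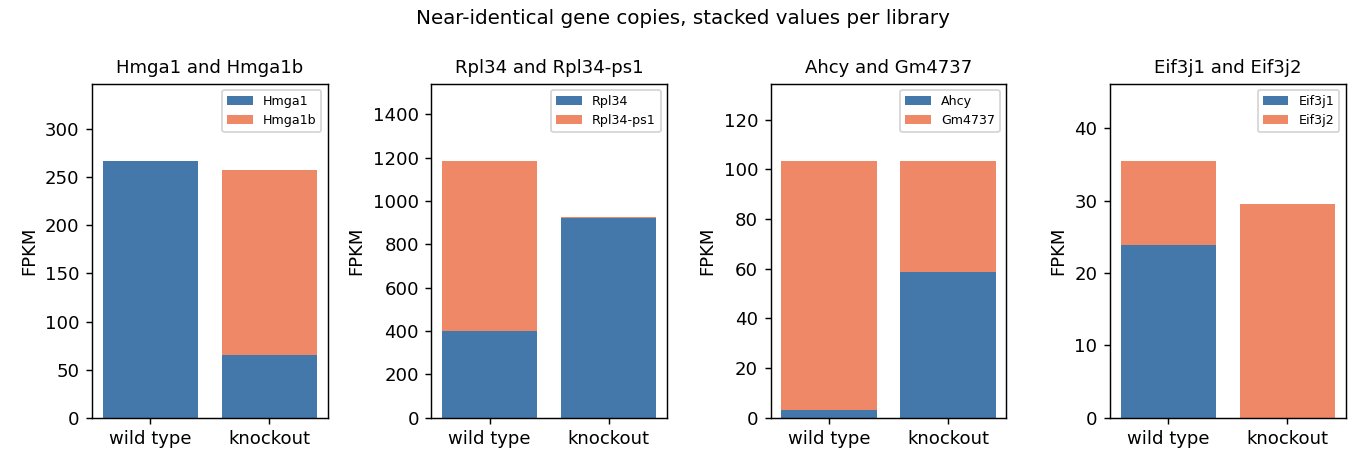
FPKM (y axis, starting at 0) of 4 genes, chosen after their values were seen, stacked with their near-identical copies, in the wild-type and knockout libraries (1 library each). The split between the copies differs between the libraries while the stacks for Hmga1 with Hmga1b (267 and 257 FPKM) and for Ahcy with Gm4737 (103 and 103 FPKM) are close in height.

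A further 29 predicted or unnamed genes with at least 5 FPKM were at least 2-fold apart and are not named. In the authors' deposited table, 3479 genes had an FDR of 0.001 or less, of which 211 had a log2 ratio of 1 or more and 413 a log2 ratio of −1 or less. That test compares the reads of the 2 libraries, not the genotypes. The gene counts depended on the treatment of low values, and the authors' log2 ratio, which adds no pseudocount, gave 201 higher and 402 lower genes among the 10998.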

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

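Alternatives with median-of-ratios scaling, reconstructed reads and summed copies were chosen after the results were seen; the others were planned. The counts of genes 2-fold apart moved with the treatment of low values, from 111 higher and 216 lower to 190 and 365 with a pseudocount of 0.1, to 29 and 75 with a pseudocount of 5, and to 201 and 402 by the authors' log2 ratio. A minimum of 5 FPKM left 60 higher and 147 lower genes. Reconstructed reads gave 305 and 576 genes with a 95% counting interval, 223 and 438 with a stricter interval, and 261 and 497 with 5 reads added; the first of these kept 101 of the 111 and 209 of the 216. A fold of 1.5 gave 298 and 571 genes and a fold of 4 gave 13 and 33. Summed copies (90 and 199), scaling by upper quartile (113 and 209) or median of ratios (113 and 205), named symbols (89 and 187) and at least 100 reads (128 and 287) stayed within 1.5 times, and more genes were lower than higher in every setting run. Dropping the FPKM minimum tested nothing, since a pseudocount of 1 keeps genes under 1 FPKM below 2-fold.

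None of the 316 alternatives for list medians reversed a median outside the central 95%; 285 kept their call, 17 lost it and 14 moved. The Th1, type I interferon, CD8 and NK, cholesterol and macrophage lists stayed outside the central 95% in 12 of 12 settings. Of the 226 alternatives for named genes, 91 moved and 3 turned sign, each when copies were summed: Hmga1b −0.0544, Ahcy −0.0012 and Hist1h2ai −0.23. The cause was not tested. No paired analysis was possible because each genotype had 1 library, and planned normalisations of counts were not run because no counts were used here. Depth limits genes with few reads, such as Il23r with 81 in the knockout.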

Other observations

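The gene families described first, and the tests that follow, were chosen after the results were seen, except the test for a single chromosomal region, which was set before its result was seen.

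Killer cell lectin-like receptors, which NK cells and activated cytotoxic T cells carry, were at least 1.5-fold lower in the knockout library in 12 of 13 measured genes, with a median log2 ratio of −1.37. All 13 lie in 1 stretch of chromosome 6, from Klrb1c at 128778485 to the end of Klra7 at 130233322, so they are not separate observations. Klrc1 went from 40.1 to 8.09 FPKM (log2 ratio −2.83 summed with its copies Klrc2 and Klrc3) and Klrd1 from 77.2 to 29.2 FPKM. All 7 measured granzyme genes were at least 1.5-fold lower, including Gzmc, from 52.6 to 9.94 FPKM. Gzmk passed narrowly, at 1.502-fold lower on 32 and 16 reads. Gzmb, Gzmc, Gzmd, Gzme and Gzmf lie together on chromosome 14, and Gzma and Gzmk on chromosome 13, so these too are not separate observations. Interferon-inducible families ran the same way: 7 of 8 guanylate-binding protein genes were at least 1.5-fold lower, with Gbp2 from 179 to 64.4 FPKM, as were 4 of 6 p200 genes, Mndal, Ifi203, Ifi209 and Ifi214. These 4 have near-identical copies in the family, so their separate values are uncertain. Mndal had a log2 ratio of −2.24 alone and −1.31 summed with its copies (9.82 to 3.37 FPKM), and Ifi209 with Ifi214 summed to −1.34. Among p200 genes under the FPKM minimum, Ifi205, a copy of Mndal, and Ifi207 ran the other way. They had 1 and 26 reads and 4 and 17 reads in the wild type and knockout, whereas Ifi206 was lower, with 21 and 4. Of the Ifitm genes, 4 of 6 were lower, and Ifitm1 went from 833 to 197 FPKM. Gbp4 and Gbp9 passed 1.5-fold narrowly, at 1.504-fold and 1.521-fold lower. The Gbp genes lie in clusters on chromosomes 3 and 5, the p200 genes on chromosome 1 and the lower Ifitm genes on chromosome 7. Members of a cluster are not separate observations.

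The TNF superfamily split, with 8 of 27 measured genes at least 1.5-fold higher and 5 lower, and a median of −0.02. The lymphotoxin genes Lta and Ltb were higher in the knockout library, from 99.3 to 306 FPKM and from 145 to 284 FPKM. Tnfrsf8, which encodes CD30, Fasl and Tnfsf11, which encodes RANKL, were lower, with log2 ratios of −1.09, −1.07 and −1.03.

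Genes 2-fold apart often had near-identical copies, 51 of 292 searched against 9 of 292 genes of matched expression. Reads shared between the copies found, as the whole cause, are argued against by 7 of 31 families, among them those of Klrc2, H2-Q2, Gbp6, Trim30a, Mndal and Ifi209, which stayed 2-fold apart in the sum with counting intervals beyond 2-fold (−2.76 to −2.43 for Klrc2), whereas sharing leaves the sum as it was. In 9 other families (29.0%) the copies changed the other way by 0.5 to 2 times the FPKM change of the gene. Among them were Hmga1, Rpl34-ps1, Eif3j1 and Rnaset2b. That share was 0% to 22.6% (central 95%, highest 29.0%) when other genes of the same level took the place of the copies. Sharing may therefore account for a part of these 9. Summed reads were close to level for Rnaset2b (interval −0.01 to 0.10). They were less so for Hmga1 (−0.31 to −0.23), Rpl34-ps1 (0.53 to 0.60) and Eif3j1 (−1.16 to −0.97), where sharing alone is uncertain. For the remaining 15 families sharing stays open because a modest change in the sum, or few reads, can hide it. A single passenger region around the deleted locus is argued against only for the 23 families whose sums fell under 2-fold. At most 4 of these share a chromosome. That test leaves out genes without copies and families that stayed 2-fold apart. Among the lower genes left out, Pianp, Klrc2 and Klra5 lie on chromosome 6 between 124996720 and 129913237, whereas Ctse lies on chromosome 1. The position of the deleted locus was not used here, so a passenger region on chromosome 6 stays open. A strain difference spread over several chromosomes was not tested and stays open, and no biological explanation was tested.

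The lower cytotoxic and NK receptor genes may reflect a different mixture of cells, although naive CD4+ T cells were the starting population per the labels. A smaller share of CD8 T cells of unchanged kind, as the whole cause, is argued against. The median of the other 6 measured genes of that list lay −0.74 from the lower of Cd8a and Cd8b1. Of these genes, 6 of 6 had counting intervals below both. Klrb1c, Klre1, Klrd1 and Klrk1 among them lie in the stretch of chromosome 6 described above, so they are not separate observations. Klrb1c, at 1.03 and 0.13 FPKM, had a log2 ratio of −0.85 on FPKM + 1 and lay lower on the read ratio (interval −4.33 to −1.81). The test cannot decide on a loss of only the CD8 T cells richest in these 6 genes, which would also lower them more than Cd8a and Cd8b1. A difference in scaling is argued against by the median log2 ratio of all genes, −0.028. Fewer NK cells as the whole cause are argued against by the wild-type level of Tyrobp and Fcer1g, which NK cells express abundantly. At 2.28 and 3.98 FPKM, they lay far below the median FPKM lost by those 6 genes. That loss was 8.92 times the higher of these levels, with 4 of the 6 past 5 times. The NK receptor genes Klre1, from 8.99 to 2.66 FPKM, and Klrb1c lost less. The argument needs NK cells not to hold the lost RNAs far above Tyrobp and Fcer1g, which was not measured. It cannot decide on NK cells that do. The median log2 ratio of Tyrobp and Fcer1g, 0.29, does not count NK cells. It rests on few reads (25 and 31 for Tyrobp, 49 and 64 for Fcer1g), and both counting intervals include no difference. A part played by NK or CD8 T cells stays open, as does a passenger region on chromosome 6 for the Klr genes. The genotype itself was not tested and stays open too.

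Within the Th17 list, Il17a, Il17f and Il23r were at least 1.5-fold lower and Il21 was at least 1.5-fold higher, while Il24, Maf and Irf4 lay within 1.5-fold with log2 ratios of 0.47, 0.48 and 0.51. A smaller share of Th17 cells as the whole cause needs the listed cytokines to be lower together, provided that only Th17 cells express them. In that case it is argued against, since Il21 had a log2 ratio of 0.90, with 3 of 5 at least 1.3-fold higher. Of these, Il22 is uncertain because of its copy Iltifb. Whether other cells in the cultures expressed Il21 or Il24 was not measured, so a smaller share of Th17 cells beside more of such cells stays open. A difference between the 2 cultures unrelated to genotype cannot be told apart from an effect of the knockout, because each genotype had 1 library.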
